A study of Arabidopsis thaliana with 3 samples.

How the data were processed

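Etiolated Arabidopsis thaliana seedlings, grown for 4 days in the dark, were compared with seedlings of the same age that then received 4 h of white light (100 µmol m-2 s-1 at 22 °C). Per the labels, RNA was purified as poly(A)+ RNA, and labelled cRNA was made from 8 ng of it for each channel. The dark RNA carried Cy5 (red) and the light RNA carried Cy3 (green) on each of the 3 arrays, which the series text calls independent biological replicates. The array was a custom Agilent design for surveying alternative splicing. All 3 arrays lay on 1 slide and were scanned together, so slide and scan could not act as a batch between them. No array had the dyes exchanged, so a dye effect of a single probe has the same form in these data as an effect of light.

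Per the file headers, the authors' scanner files came from Agilent Feature Extraction 10.7.1.1. The deposited intensity columns give the median pixel brightness of each spot and of its local background in both channels, without normalization. Per the file headers, the processed intensity columns were background-subtracted, spatially detrended and dye-normalized by the same software, and the deposited log10 ratio is red over green, so its sign was turned here to give light over dark. The deposited spot marks (other columns, coded 0 or 1) state whether a spot was well above background, saturated or an outlier. The authors' value table holds log2 ratios of green over red. Its values were set against the log10 ratios of each array and differed from them by at most 0.000502 after the change of base, so its scale and direction are known, and its centring is that of Feature Extraction. Its column medians were -0.047, -0.043 and -0.046. The table gives values for 66465 of its 173896 probes. Each of these was well above background in both channels on all 3 arrays, and 60529 further probes that met the same condition have no value there. How those rows were chosen is not given in the sources used here.

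From the deposited intensities, the background was corrected with normexp (offset 50), the log ratios were normalized within each array by loess with control spots at weight 0, and control spots were then left out. The design fixed before the data were examined named mean spot signals. The files hold median signals, and these were used in their place. In all, 34 spots of non-control probes marked as outliers were set to missing. A probe was tested if it was well above background in at least 1 channel on each of the 3 arrays, which left 135964 of 173896 probes. The log2 ratio of light over dark was tested against 0 with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. "Rose" and "fell" refer to this test. Brightness is the average log2 intensity of both channels after loess.

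Probe names gave a gene only for 28 probes, of which 14 carry the symbol CCA1 alone and 14 carry it after the prefix M. The values for CCA1 come from the first 14. The M-prefixed ones were left out of them, since the meaning of that prefix is not given in the sources used here. The reference table (TAIR10.1 assembly, used for names only) pairs this symbol with the locus AT2G46830. The other 173868 probes were not paired with genes in the sources used here, and probe sequences were not used here. Gene values, the gene lists fixed beforehand, their direction check, a splicing index across genes, its summary by probe class and the overlap of splicing with level were therefore not computed. The fixed rule for named genes (the largest changes past the threshold with the same sign on all 3 arrays) was applied to probes measured in both channels, and 2 probe IDs that rose and 2 that fell are given. Class medians by the prefix of the probe name took the place of the planned splicing index by class, and were chosen after the data were seen. What the prefixes stand for is not given in the sources used here. For CCA1 the index was computed as designed, as a probe's log2 ratio minus the mean of the gene's other probes on the same array, over probes well above background in both channels on all 3 arrays.

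Class medians were compared on each array, over all probes and within brightness bins with edges at 7, 8, 9, 10, 11 and 12 weighted by the number of probes of the class. These used an exact two-sided sign-flip permutation test over the 3 arrays, whose smallest possible p is 0.25. For neighbours in probe number, an unprefixed probe's log2 ratio was set against the mean log2 ratio of the nearest measured probe on either side, at most 2 numbers away, where these differed by at most 0.5. It was called deviating at an adjusted p under 0.05 (limma) and a deviation of at least 1 (log2).

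The probe test was tested on simulated data with a spread taken from these arrays. With 200 of 135937 probes changed, it recovered 0% of changes of 0.5, 53.7% of changes of 1 and 89.4% of changes of 2 (log2), with 0 false calls. With 67968 probes changed, 96.3%, 99.8% and 100% were recovered, with 1942 false calls among 67969 unchanged probes. These figures hold for the simulated probes only. In the fit to the arrays the median SE of a tested probe was 0.072 (log2). A change of 0.5 is large against that SE, so the 0% above cannot be read as the power of the test here. The neighbour test was run on separate simulated probes with a constant spread, in blocks of equal ratios, with each deviation upward and inside a block. It found 200 of 200 deviating probes and called 0 others. That setting is simpler than these arrays, so it does not give the error rate here. The number of arrays limits the precision of all values. The alternatives were no background correction, the Agilent processed log ratios, median centring, the authors' value table, other detection filters, leaving out saturated probes or each replicate, 6 channels as separate samples, another variance prior, a 2-fold threshold and, added after the data were seen, the Agilent processed log ratios scaled to the E1A spike-ins. That setting changes 2 choices together: it takes the Agilent log ratios in place of loess and then shifts each array by 1 constant. The closing part gives their effect.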

Results

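The arrays measured transcript levels in dark-grown Arabidopsis seedlings and in seedlings given 4 h of white light, the switch that starts photomorphogenesis (the change from growth in the dark to greening growth in the light). There was 1 comparison, light over dark, with 3 arrays that each held 1 dark and 1 light RNA. Of the 173896 probes on each array, 77.4%, 76.9% and 76.4% were well above background in the light channel of replicates 1, 2 and 3. In the dark channel these shares were 79%, 78.5% and 77.4%. No spot was saturated. The median signal over local background was 147, 154 and 164 in the light channel and 279, 225 and 216 in the dark channel. Log2 ratios correlated between arrays across probes (Pearson r of 0.95, 0.967 and 0.959 for the 3 pairs), and probes are not independent replicates.

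The first question was how widely transcript levels differed after 4 h of light. Of 135964 tested probes, 47747 rose and 45100 fell in the light (limma, adjusted p under 0.05), which is 68.3% of those tested. As no array had the dyes exchanged, these counts also hold any fixed dye effect of single probes, which cannot be told apart from light. Most of these changes were small: the median log2 ratio was 0.54 among probes that rose and -0.42 among those that fell, and 82.6% of them changed by less than 2-fold. Large changes went mainly upward after loess. At 2-fold or more, 11251 probes rose and 4891 fell, a ratio of 2.3, and at 8-fold or more 388 rose and 154 fell. The median SD of a probe's log2 ratio over the 3 arrays was 0.11. The balance of directions depended on the centring. With median centring in place of loess, 33250 probes rose and 65034 fell (33.8% of calls upward, against 51.4%), and at 2-fold or more 7060 rose and 10676 fell. That centring moved the median of all tested probes to -0.17, so each direction is relative to the zero that the normalization sets. The Agilent processed log ratios put that median at -0.09, with 40871 rising and 51476 falling probes. Scaling those same ratios to the E1A spike-ins put it at 0.45, with 32393 rising and 4453 falling. The spike-in offset taken away was 0.18, -0.75 and -1.05 (log2 light over dark) in replicates 1, 2 and 3. Replicate 1 thus moved down and the others up, so these counts rest on spike-ins that differed between arrays.

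The largest rises and falls reached far beyond the spread between arrays. Probe probe_053925_819 rose by 6.02 ± 0.14 (log2, SD, n = 3; adjusted p = 2e-14 by limma), and probe_J068206_819 rose by 5.99 ± 0.12 (adjusted p = 2e-14 by limma). Probe probe_118145_819 had a log2 ratio of -4.75 ± 0.21 (SD, n = 3; adjusted p = 2.1e-13 by limma) and probe_003833_819 one of -4.75 ± 0.07 (adjusted p = 5.1e-14 by limma). By the rule that picked them, each of these held its sign on all 3 arrays and was well above background in both channels. The genes behind them are not given in the sources used here.

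**Figure D1:**
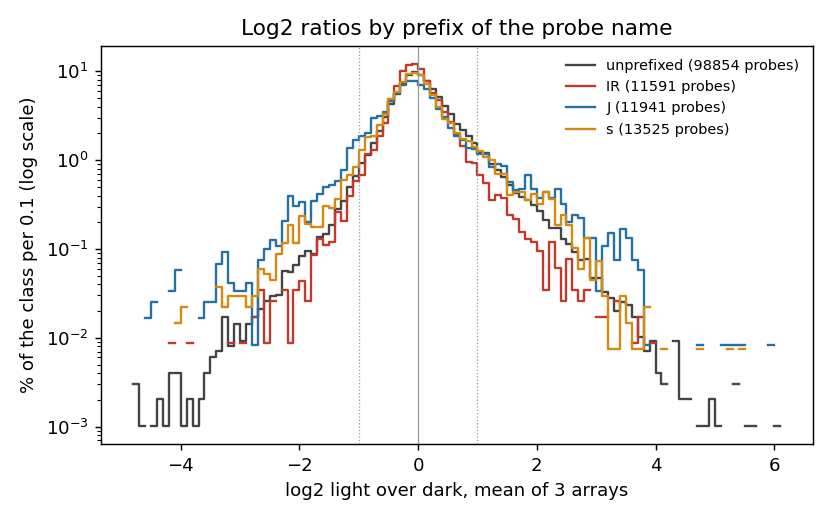
Share of probes in each 0.1 step of the log2 ratio of light over dark (mean of 3 arrays, x axis; share in percent on a log scale, y axis), by prefix of the probe name; dotted lines mark 2-fold. After loess 8.3% of all tested probes rose and 3.6% fell by at least 2-fold; with median centring the balance turns, with 7060 probes rising and 10676 falling.

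The array carries several classes of probe, told apart by the prefix of the name, and the second question was whether they responded alike, as the array was made to survey splicing. Among unprefixed probes 36295 of 98854 rose and 31092 fell. Among IR-prefixed probes the balance was the other way, with 3158 of 11591 rising and 4063 falling. J-prefixed probes (3929 of 11941 rising and 4984 falling) and s-prefixed probes (4353 of 13525 rising and 4949 falling) also fell more often than they rose when changes of any size were counted. At 2-fold or more, rises outnumbered falls in all 4 classes after loess, by 8234 to 2939 among unprefixed probes (a ratio of 2.8), 439 to 255 among IR-prefixed probes (1.72), 1348 to 1038 among J-prefixed probes (1.3) and 1226 to 652 among s-prefixed probes (1.88). For IR-prefixed probes this came from the dimmer ones: between 7 and 8 in brightness 7.5% rose and 4.5% fell by 2-fold or more. In each bin from 9 up falls equalled or outnumbered rises (8.7% rising and 10.5% falling between 9 and 10). Those bins held only 229, 102, 42 and 37 IR-prefixed probes, so the differences there rest on few probes and do not establish a turn of direction. Among J-prefixed probes falls outnumbered rises only between 11 and 12 (12.8% rising and 15% falling). Over 12 their rises again outnumbered falls (23.1% rising and 17.9% falling).

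The median log2 ratio of IR-prefixed probes was -0.05 ± 0.01 (SD, n = 3) and that of unprefixed probes 0.02 ± 0.01, a difference of -0.073 ± 0.013. Within brightness bins the difference was -0.067 ± 0.013 (SD, n = 3; exact sign-flip p = 0.25, the smallest the design allows), and it lay below 0 on each of the 3 arrays. Over the same bins J-prefixed probes lay lower than unprefixed ones by a difference of -0.112 ± 0.007 and s-prefixed probes by one of -0.059 ± 0.009, with the same exact p of 0.25. For 12864 s-prefixed probes measured together with the unprefixed probe of the same number, the median difference was -0.007 and the unprefixed partners had a median of -0.025. The IR difference was larger among brighter probes. In bins above a brightness of 8 it was -0.212 ± 0.017 (SD, n = 3), and there 575 of 1136 IR-prefixed probes fell (50.6%) and 333 rose (29.3%), against 33.3% and 39.4% of 66968 unprefixed probes. With median centring, falls outnumbered rises there in both classes. Among IR-prefixed probes 767 fell (67.5%) and 221 rose, and among unprefixed probes 38659 fell (57.7%) and 14560 rose. The same held for J-prefixed probes (5683 fell and 1947 rose) and s-prefixed ones (5521 fell and 1897 rose). Over all brightnesses, without matching, median centring turned the IR difference to 0.212 ± 0.118, while among the brighter probes it stayed at -0.203 ± 0.021. Only 48.3% of the IR-prefixed probes were bright enough to test, against 81% of the unprefixed ones.

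**Figure D2:**
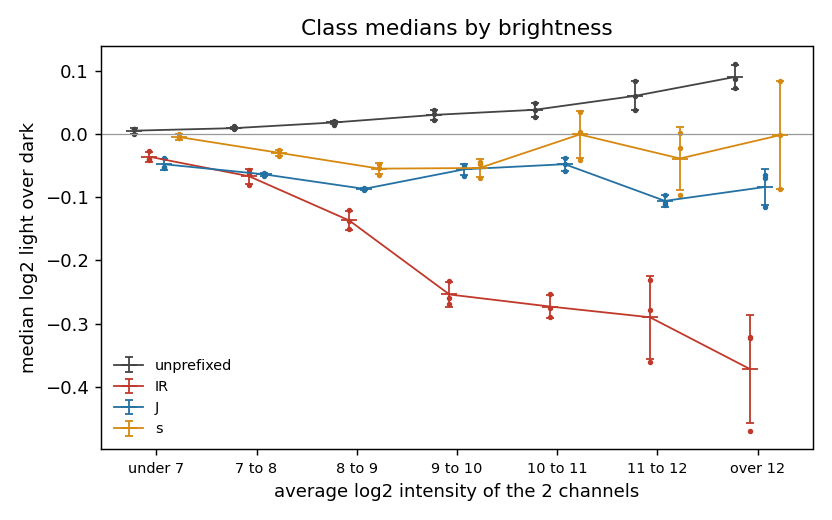
Median log2 ratio of light over dark (y axis) in bins of average log2 intensity (x axis) for 4 classes of probe; points are the 3 arrays, and bars give the mean and SD (n = 3). IR-prefixed medians go from -0.036 in the dimmest bin to -0.254 between 9 and 10, while unprefixed medians stay between 0.005 and 0.09; under median centring the unmatched IR difference turns to 0.212.

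CCA1 (AT2G46830), a MYB transcription factor of the core circadian clock, was the gene that probe names identified. Of the 14 probes named CCA1 without a further prefix, 10 were well above background in both channels on all 3 arrays. The median log2 ratio over these 10 probes was 0.53 in replicate 1, -0.33 in replicate 2 and -0.06 in replicate 3, with a mean of 0.04 ± 0.44 (SD, n = 3; exact sign-flip p = 1). The mean was thus smaller than the spread between replicates, which leaves the size and direction of a CCA1 shift undetermined. The mean was -0.2 without replicate 1 (SD 0.19), 0.23 without replicate 2 (SD 0.42) and -0.2 with median centring (SD 0.46). Scaling the Agilent log ratios to the E1A spike-ins gave 0.58 (SD 0.32), larger than its spread, though the spike-ins differed between arrays. With all 3 arrays and loess, CCA1 probe 14 was the 1 probe of the 10 that passed the test over all probes, with a log2 ratio of 0.36 ± 0.49 (SD, n = 3; adjusted p = 0.027 by limma), above 0 on 2 of 3 arrays. None of the 10 probes passed when adjusted over the list alone (limma, 0 probes, against 1 at an unadjusted p under 0.05). The calls depended on the arrays used: without replicate 1, 4 of the 10 probes fell and 0 rose, and without replicate 2, 6 rose and 0 fell. With median centring 1 rose and 5 fell. The call of probe 14 was lost without replicate 1 (log2 ratio of 0.08, adjusted p = 0.48 by limma) and with median centring (0.00, adjusted p = 0.99 by limma). It was also lost, at log2 ratios of 0.30, 0.36, 0.36 and 0.84, with the Agilent processed log ratios, 6 channels as separate samples, the other variance prior and the Agilent ratios scaled to the spike-ins (adjusted p of 0.23, 0.13, 0.17 and 0.1 by limma). Of the 14 M-prefixed CCA1 probes, 5 were tested and 0 were called (limma; 0 at an unadjusted p under 0.05).

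The last question was whether parts of the CCA1 transcript responded differently, as measured by the splicing index. None of the 10 probes had a changed index (limma, 0 probes after adjustment, 1 at an unadjusted p under 0.05, and 0 by limma diffSplice at either level). The index was highest for probe 14, at 0.30 ± 0.11 (SD, n = 3; adjusted p = 0.075 by limma), above 0 on all 3 arrays, and lowest for probe 1, at -0.17 ± 0.08 (adjusted p = 0.5 by limma). These p-values rest on a spread pooled over the probes: each index had an SE of 0.1, though SDs ran from 0.05 to 0.45. The largest SD was that of probe 2, at -0.46, 0.40 and 0.17 in replicates 1, 2 and 3. Probe 2 also enters the reference mean of each other probe. The count was 4 without replicate 1, 5 with median centring and 3 with the Agilent processed log ratios, so the absence of calls does not hold across settings.

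**Figure D3:**
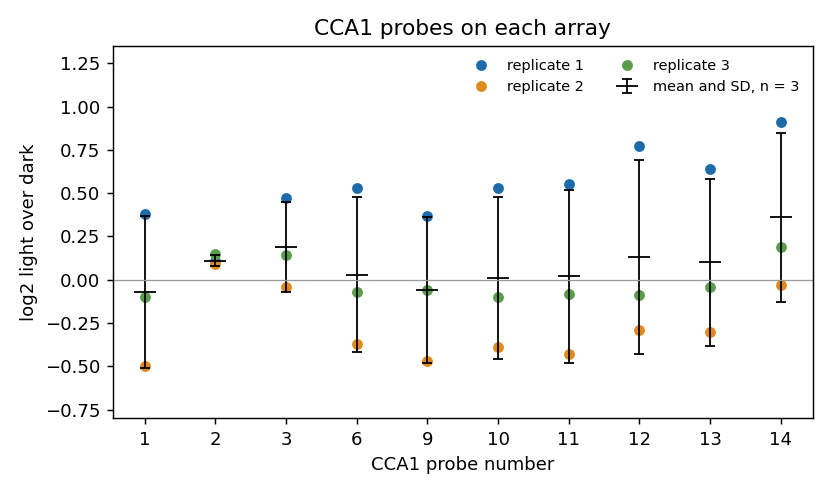
Log2 ratio of light over dark (y axis) of the 10 measured CCA1 probes (x axis, probe number) on each array, with mean and SD (n = 3). Replicate 1 lies between 0.11 and 0.91, replicate 2 between -0.5 and 0.09 and replicate 3 between -0.1 and 0.19.

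Neighbouring probe numbers gave similar ratios, so probes cannot be counted as independent measurements. Across 56901 pairs of unprefixed probes with consecutive numbers, log2 ratios correlated with r = 0.811, falling to 0.248 at a distance of 10 numbers and 0.007 at a distance of 50. Shuffled ratios gave at most 0.011 in size at distance 1 over 20 shuffles. The 7978 unprefixed probes that were measured in both channels and rose at least 2-fold formed 2796 runs of neighbouring numbers, and 71.7% of them stood in runs of 3 or more. The 2836 that fell at least 2-fold formed 1282 runs, with 58.5% in runs of 3 or more. These correlations are across probes, which are not independent replicates.

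**Figure D4:**
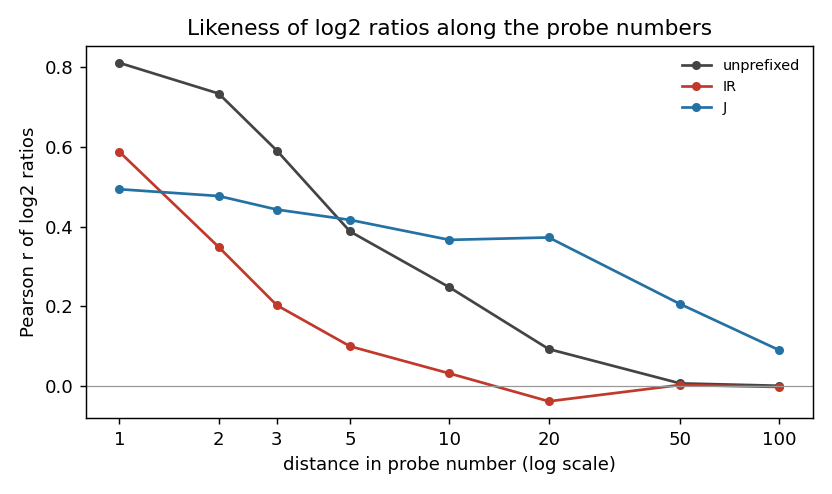
Pearson r of log2 ratios between probes of the same class (y axis) against their distance in probe number (x axis, log scale). Unprefixed probes fall from 0.811 at distance 1 to 0.007 at distance 50, while J-prefixed probes still give 0.206 there.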

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

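The tests on the spike-ins were chosen after the result was seen. Control probes outside the comparison gave signal above the 600 negative control spots per array, of which 0.7% were well above background in green and 0.6% in red. Of 10 E1A spike-in probes, which detect RNAs added to each labelling reaction, 9 were well above background in both channels on over 50% of their spots. So were 14 control probes with names starting in DCP. The control probe ERCC-00062_278 was well above background on 75% of its red and 41.1% of its green spots, while the other ERCC probes reached at most 1.7%.

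The E1A ratios differed between arrays. After loess, the median E1A probe had a log2 ratio of green over red lower by a difference of -0.69 in replicate 2 and -0.93 in replicate 3 than in replicate 1, and each of the 10 probes was lower in replicate 3 (differences from -1.29 to -0.37). Normalization within the array was argued against as the whole source, since the signal of the spike-ins over the sample already ranged by 1.04 (log2) between arrays before it in the red channel. That range was 6.41 times that of the green channel, which is consistent with unequal amounts of spike-in or of dark RNA in the red labelling, and these remain open. A true difference in total mRNA between dark and light seedlings was not tested, as it would need equal spike-in amounts per seedling.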

How the results depend on the processing

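Scaling of the Agilent processed log ratios to the E1A spike-ins (which replaces loess as well) and the comparisons of probe classes and of the CCA1 median were added after the data were seen. The counts of 47747 rising and 45100 falling probes stayed within 1.5 times under no background correction, the Agilent processed log ratios, median centring, both other detection filters, the other variance prior and without each replicate (42674 to 46532 rising and 38579 to 43823 falling). The balance of directions nonetheless turned within that margin. With median centring 33250 rose and 65034 fell, and with the Agilent processed log ratios 40871 rose and 51476 fell. With no replicate block, taking the 6 channels as separate samples, 44616 rose and 41345 fell. Leaving out saturated probes removed none. The authors' value table, which holds fewer probes, gave 22167 and 24657, the 2-fold threshold 11251 and 4891, and spike-in scaling 4453 falling. The IR difference of -0.073 became -0.122 with the Agilent processed log ratios, with or without spike-in scaling, which adds 1 constant per array to them, -0.15 in the authors' value table, -0.032 with no filter on dim probes and 0.212 with median centring. In brightness bins these were -0.144, -0.172, -0.032 and -0.037. The median CCA1 log2 ratio moved from 0.04 to 0.03 with the Agilent processed log ratios and 0.58 once these were scaled to the spike-ins, to -0.2 with median centring, and ranged from -0.2 to 0.23 without 1 replicate. The moves other than by spike-in scaling were smaller than its SD of 0.44. The number of CCA1 probes with a changed splicing index was 3 with the Agilent processed log ratios, 5 with median centring, 1 with the median of the other probes as reference, 1 with no replicate block and 0 to 4 without 1 replicate. Single CCA1 probes changed sign with median centring (-0.26 for probe 6, -0.17 for probes 10 and 12, -0.22 for probes 11 and 13), where probe 14 went to 0.00. With the Agilent processed log ratios, probe 6 was at -0.04, probe 10 at 0.00 and probe 11 at -0.07. With spike-in scaling, probe 1 was at 0.47 and probe 9 at 0.36. With 1 replicate left out, probe 1 ranged from -0.30 to 0.14, probe 6 from -0.22 to 0.23, probe 9 from -0.27 to 0.15, probe 10 from -0.24 to 0.22, probe 11 from -0.25 to 0.24, probe 12 from -0.19 to 0.34 and probe 13 from -0.17 to 0.30. CCA1 probes called numbered 6 with median centring, 0 to 6 in all settings with values, and 1 to 6 without 1 replicate. Where no construction is named, the cause was not tested. The 4 probes named by ID kept their calls in each setting that measured them. Not run were all alternatives for gene values, gene lists and the index across genes, which need a probe-to-gene table, the value table for CCA1, whose 28 probes have no values there, and the slide as a block, since there was 1 slide. No alternative is given here for the deviating probes, the runs and correlations along probe numbers, or the J-prefixed and s-prefixed median differences. Signal over background limits which probes could be tested, with 48.3% of the IR-prefixed and 81% of the unprefixed ones.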

Other observations

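The tests below on the IR-prefixed probes, on dye bias and on single-spot noise were chosen after the result was seen, while those on weak signals and on sign patterns were written before. Of 62804 unprefixed probes with agreeing neighbours in probe number, 8623 differed from the mean of these neighbours at any size (limma, adjusted p under 0.05). Among them 206 deviated from that mean by at least 2-fold, 104 above and 102 below it. In 23 of the 206 the probe and its neighbours had opposite signs, each at 0.5 or more in size. Such a probe is what a part of a transcript that responds to light unlike the rest would give, if neighbouring numbers share a gene, which is a hypothesis that the sources used here cannot settle. Noise of single spots was argued against for the 24 deviating probes that had a measured s-prefixed probe of the same number: all 24 deviated the same way, with a median of 0.96 of the deviation. The other 182 had no such partner. Compression of the deviating probe's own weak signal was argued against as the whole source, as 27.2% of these probes had a smaller ratio in size than their neighbours. Compression of the neighbours was not tested, since it would give the deviating probe the larger ratio. The deviating probes had a median brightness of 9.45, against 8.89 for the other probes tested. Dye bias of these probes cannot be told apart from light, with 0 arrays of exchanged dyes.

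IR-prefixed probes had lower median ratios in light than unprefixed ones. Bias with brightness was argued against for probes brighter than 8, where the difference was -0.212 ± 0.017 in the same brightness bins. Over all bins it was -0.067 ± 0.013, but 7696 of the 11591 IR-prefixed probes lay in the open bin under 7. Brightness is matched only loosely in that bin, so such a bias remains open for the dim probes. Normalization remains open for the class as a whole, as median centring turned the unmatched difference to 0.212, a value that also holds the difference in brightness between the classes. In the same brightness bins that setting gave -0.037 ± 0.03, about as large as its spread over the arrays, and no background correction, the Agilent processed log ratios and the authors' value table gave -0.077, -0.144 and -0.172. Normalization was argued against as the source of the matched difference for probes brighter than 8. There the highest difference over the other processings was -0.203 ± 0.021, with median centring. That value follows largely from the matching, since a shift set by brightness alone nearly cancels between classes in the same bin. It is therefore not a separate test of the centring. Without background correction the difference was -0.219 ± 0.017. Dye bias of these probes cannot be told apart from light, again with 0 arrays of exchanged dyes, and J-prefixed probes also lay below unprefixed ones. The s-prefixed probes did so as a class, but by a median of -0.007 against the unprefixed probes of the same number. An effect of light on the targets of these probes stays open and was not tested separately.

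The number of probes changed in level was set against the 4 ways of turning the sign of whole arrays. The real signs gave 92847 changed probes and 206 deviating ones, and the highest other pattern gave 0 of either, with 1 of 4 patterns reaching each real count. With 4 patterns, no share under 0.05 can be reached.

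The 10 measured CCA1 probes were higher in replicate 1 than in replicate 2, by a median of 0.91 (log2), while for 60909 unprefixed probes in the same range of brightness the same difference had a 5th percentile of -0.34 and a 95th percentile of 0.36. Of the CCA1 probes 9 lay above that range, and probe 2, with a difference of 0.02, lay inside it. Light RNA alone gave signal (well above background on 3 arrays in green and on 0 in red) for 1259 probes, and dark RNA alone for 2181. IR-prefixed probes made up 616 and 1125 of these. The red channel had more probes well above background on each array (137359 against 134672 in replicate 1), and no dyes were exchanged. An excess of dark-only probes can therefore not be told apart from a difference between the channels. The s-prefixed probes gave nearly the ratios of the unprefixed probes of the same number, with r = 0.99 across 12864 pairs and 0.062% of pairs apart by 2-fold or more.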
